A study of Rattus norvegicus with 10 samples.

How the data were processed

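The series held 10 Affymetrix rat expression arrays, each hybridised with RNA from 1 mammary tumor sample. Tumors had been induced in female Sprague-Dawley rats with a single oral dose of 100 mg/kg of the carcinogen DMBA. Each of 5 tumors, coded 09I1, 11D2, 12I1, 29I1 and 43D1, gave a basal needle biopsy at 12 weeks of age and a final sample at 19 weeks (called a needle sample in the design text and the whole tumor in the sample labels), after adriamycin (doxorubicin, an anthracycline) at 1 mg/kg per week for 6 weeks. The groups therefore held 5 samples each, paired by tumor. The sources used here do not say whether each tumor came from a separate rat, so p-values measure the spread between tumors, some of which may share an animal.

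The deposited values are on the log2 scale. Per the labels' protocols, the authors normalized intensities with robust multichip averaging, removed control sequences and signals close to background without a stated limit, and tested pairs with Student's test in GeneSpring GX 7.3. The table used here still held 57 control probe sets and all levels of signal, so that filter is not part of it. It had 31099 probe sets. Of these, 20826 carried 1 gene symbol in the platform annotation, 436 carried several and 9780 carried none. Of the probe sets with 1 symbol, 20764 matched the RefSeq table of the GRCr8 assembly by Entrez identifier, and no symbol changed. That assembly served for names only. No coordinates are given, since the table names no genome build.

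Control probe sets and the 25% of the others with the lowest mean over all 10 arrays were left out, which left 23281 probe sets. Final minus basal was fitted with limma 3.58.1 in R 4.3.3, with the tumor as a block and an intensity trend in the variance. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, with a threshold of 0.05. A gene was represented by its brightest tested probe set with that symbol alone, which gave 12255 genes. The 27 gene lists held 605 entries, of which 534 matched a measured gene. They were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list's genes move on balance in one direction, without comparing them with other genes.

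The groups, tests, alternatives, gene lists and rule for named genes were fixed before the data were examined. Genes were named by adjusted p under 0.05 with the same sign in all 5 tumors. None qualified, so the 6 per direction with the same sign in all 5 tumors and the smallest p are named, as values not past the threshold. To these were added the members of each list with the smallest p, up to 4, and the fixed genes Top2a, Top2b, Abcb1a, Abcb1b, Cdkn1a, Mdm2, Mki67, Esr1, Pgr and Gapdh. Lists past camera's threshold have 4 members considered and the others 2, a number chosen after the calls were known. Abcb1a, Abcb1b and Gapdh had no tested probe set of their own and were not analysed here as genes.

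The pairing comes from the labels, which give both samples of a tumor the same code. As a check, each sample's deviation from its group mean was correlated across probe sets with that of the other sample of its tumor. The correlation was 0.072 in 09I1, 0.095 in 11D2, 0.014 in 12I1, -0.15 in 29I1 and 0.22 in 43D1. In 2 of the 5 tumors the basal sample correlated best with its own final sample. The number of arrays whose closest array was the other one of its tumor was 0. In a fit with the tumor as a random block, the estimated correlation within tumors was 0.0017. The arrays thus gave little support for the pairing, which rests on the labels.

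Simulated arrays had the real means and pairing of the comparison of final with basal samples. Their spreads were those moderated by limma, not the raw ones, which may favour the fit. The fit was tested on these arrays, over 23281 probe sets with 200 changed. It recovered 33.5% of changes of 1 log2 unit with 2 false calls, 96% of changes of 2 units with 10 and 99.5% of changes of 3 units with 8. A simulated rise of 0.5 in the endothelium list was recovered with a median of 0.56, and none of the other lists was called. The simulation drew genes independently, which real genes are not. It also gave all arrays of a probe set 1 spread. In the data, the SD of the changes was 0.89 in 09I1 and 0.47 to 0.58 in the other tumors, so recovery there may differ.

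Alternatives were no block, a random block, no filter, a filter on the lowest 50%, cyclic loess, centring on each array's median, array weights, no intensity trend and the methods' paired t-test. Further ones were the mean over a gene's probe sets, both list tests named above, a fold threshold and leaving out each tumor. No detection calls were used here, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.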

Results

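Expression was measured on 10 arrays from 5 DMBA-induced rat mammary tumors, each sampled as an untreated basal biopsy (n = 5) and as a final sample after 6 weekly doses of adriamycin (n = 5). DMBA is a carcinogen that induces hormone-dependent mammary tumors in rats, and adriamycin inhibits topoisomerase II. The comparison asks which transcripts differed within a tumor between the 2 samplings. No untreated tumor was sampled at the later time. Treatment and age therefore changed together between the groups. The kind of sample may differ too, since the sample labels call the final sample the whole tumor and the design text calls it a needle sample. The array codes in the labels form a separate run in each group, so a batch of arrays and the group cannot be told apart. The array median lay between 5.93 and 6.11 log2 units.

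The final array of tumor 09I1 stood apart from the others. Its median correlation with the other arrays, across probe sets, was 0.938, against 0.975 to 0.984 for the other 9. Its 3' beta-actin control probe set exceeded the 5' one by 2.61 log2 units, against 0.72 to 0.96 on the other 9 arrays. Its poly-A spike-in controls averaged 7.87, against 5.34 to 5.80. The SD of the changes across probe sets was 0.89 in 09I1 and 0.47 to 0.58 in the other 4 tumors.

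**Figure D1:**
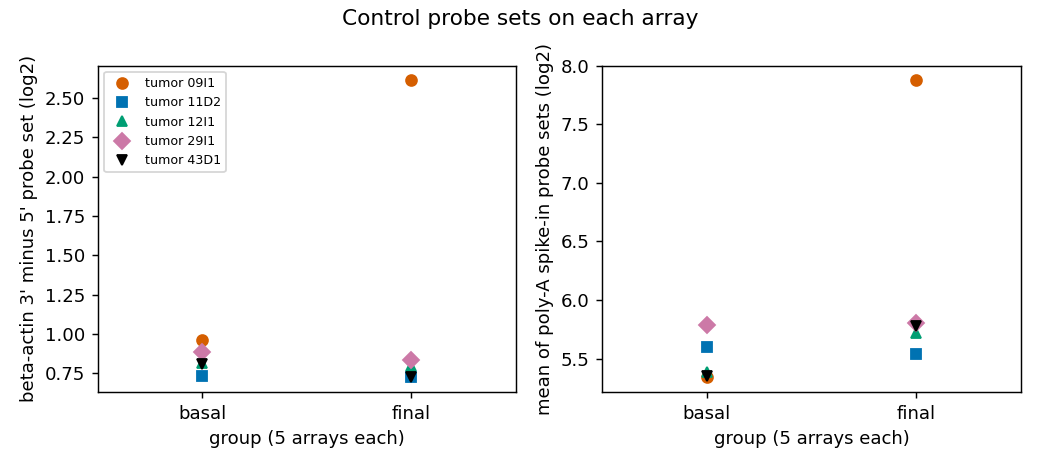
Control probe sets on each array, with the group on the horizontal axis and log2 units on the vertical axes, and 1 point per array. The final array of tumor 09I1 lies above the other 9, at 2.61 for the beta-actin difference and 7.87 for the mean of the poly-A spike-ins.

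No single gene rose or fell past the threshold across the 5 tumors. The gene with the smallest p was Cdc25b, a phosphatase that activates cyclin-dependent kinases. Its level was 8.33 ± 1.06 (SD, n = 5) in basal and 6.40 ± 0.97 (SD, n = 5) in final samples. The log2 change was -1.93 ± 0.20 (SE), negative in 5 of 5 tumors, with limma adjusted p = 0.311. Npy, which encodes neuropeptide Y, had a change of -2.39 ± 0.32 (SE), from 9.18 ± 1.27 (SD) to 6.79 ± 1.06 (SD), negative in 5 of 5 tumors, with limma adjusted p = 0.850. Alas2, the erythroid enzyme of haem synthesis, had a change of -3.15, and Hbb, a beta-globin, one of -2.22. Ccbe1, involved in lymphatic growth, had a change of -1.08, and the platelet receptor gene Clec1b one of -1.42. The final mean of Clec1b (3.42) lay below the lower quartile of every array, so the size of its change is uncertain. In the other direction, Itgbl1 had a change of 1.39, LOC102552398 one of 1.59, Cpxm2 one of 1.27 and Rab17, an epithelial trafficking GTPase, one of 1.08. Igsf5, a junction protein gene, had a change of 0.90, and Swi5, a DNA repair gene, one of 0.71. These 12 genes had the same sign in 5 of 5 tumors, and each of the last 10 had an adjusted p of 0.850.

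**Figure D2:**
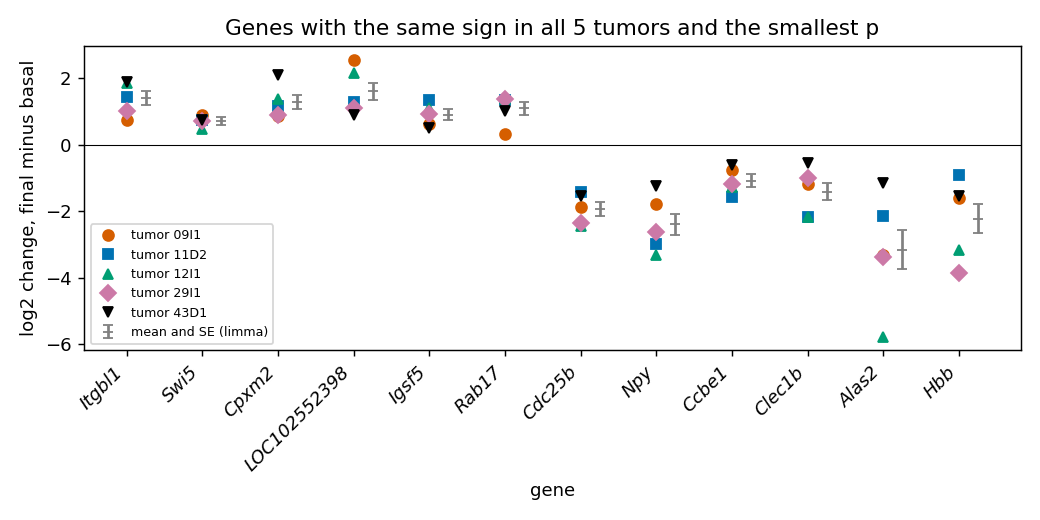
Log2 change, final minus basal, of the 12 genes with the same sign in all 5 tumors and the smallest p, with 1 point per tumor and the limma mean with its SE in grey. Alas2 has the most negative mean, at -3.15, and none of the genes passed the threshold.

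With limma, 0 probe sets were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.233. At an unadjusted p under 0.05 there were 935 of 23281, of which 399 were higher and 536 lower, where chance alone gives about 1164. The count was 1868 without 09I1 and 2440 with array weights, above the chance number, but 608 to 1076 without any 1 of the other tumors. The share higher among such probe sets was 42.7%, 37.3% with cyclic loess and 51.6% after centring on each array's median. The balance of higher and lower thus depends on the scaling. The methods' paired t-test gave 0 after Benjamini-Hochberg adjustment. Of the 12255 genes, 715 (5.83%) had the same sign in all 5 tumors, and chance gives 6.25%.

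Red blood cell genes were lower in the final samples. All 7 tested members of the list had negative mean changes, with a median of -0.90, and the list's median was negative in 5 of 5 tumors. Alas2 and Hbb fell when adjusted over the list alone, which passed 2 members, and 0 passed over all probe sets. Ahsp, a chaperone of alpha-globin, had a change of -0.90 and the blood group gene Rhd one of -0.91. Camera's adjusted p was 5.4e-07, and the adjusted p was 0.459 with an estimated correlation. In 29I1 and 43D1 the list medians were -0.22 and -0.15, and 3 of the 7 members were positive in each. The median was -0.84 without 09I1 and -0.47 without 12I1 (adjusted p = 2.1e-04).

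Genes of milk proteins and alveolar differentiation were higher, with a median of 0.53 over 14 tested members and positive list medians in 4 of 5 tumors. Elf5, a regulator of alveolar differentiation, had a change of 1.30 ± 0.30 (SE), and Wap, the whey acidic protein, one of 1.27 ± 0.33 (SE). Both rose when adjusted over the list alone, which passed 2 members, and 0 passed over all probe sets. Lalba, the milk protein alpha-lactalbumin, had a change of 1.28 and Xdh, a milk fat globule enzyme, one of 0.52. By tumor, Lalba ran from -0.27 in 11D2 to 3.54 in 43D1. Camera's adjusted p was 1.2e-05, and the adjusted p was 0.459 with an estimated correlation. The list median was -0.20 in 11D2 and lay between 0.50 and 0.95 in the other 4 tumors.

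Cell cycle and mitosis genes moved in opposite directions in different tumors. The list was lower by camera, with a median of -0.54 over 30 members (adjusted p = 1.2e-05), and the adjusted p was 0.833 with an estimated correlation. No member passed the threshold, over all probe sets or over the list alone. The list median was 1.53 in 09I1, -0.21 in 11D2, 0.26 in 12I1, -1.99 in 29I1 and -2.32 in 43D1. In 29I1 and in 43D1, 29 of the 30 genes were lower, while in 09I1, whose final array stood apart, 29 of the 30 were higher. Mki67, a proliferation marker, had changes of 1.23 in 09I1, -2.00 in 29I1 and -2.69 in 43D1, and Top2a, a target of adriamycin, had changes of 1.14, -1.63 and -2.82. The means over 5 tumors were -0.78 for Cenpf, -0.69 for Kif23, -0.56 for Hmmr and -0.65 for Racgap1. Without 09I1 the median was -1.05. Without 29I1 the median was -0.092 (adjusted p = 0.106) and without 43D1 it was -0.086 (adjusted p = 0.200). DNA replication genes had list medians of 1.56 in 09I1, -1.09 in 29I1 and -0.93 in 43D1. Their median over 23 members was -0.089, with Mcm4 at -0.33 and Fen1 at -0.26, and did not pass (adjusted p = 0.240), whereas without 09I1 it was -0.47 with adjusted p = 4.7e-09 and with array weights -0.28 with adjusted p = 6.8e-05. With an estimated correlation these 2 adjusted p-values were 0.692 and 0.697.

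**Figure D3:**
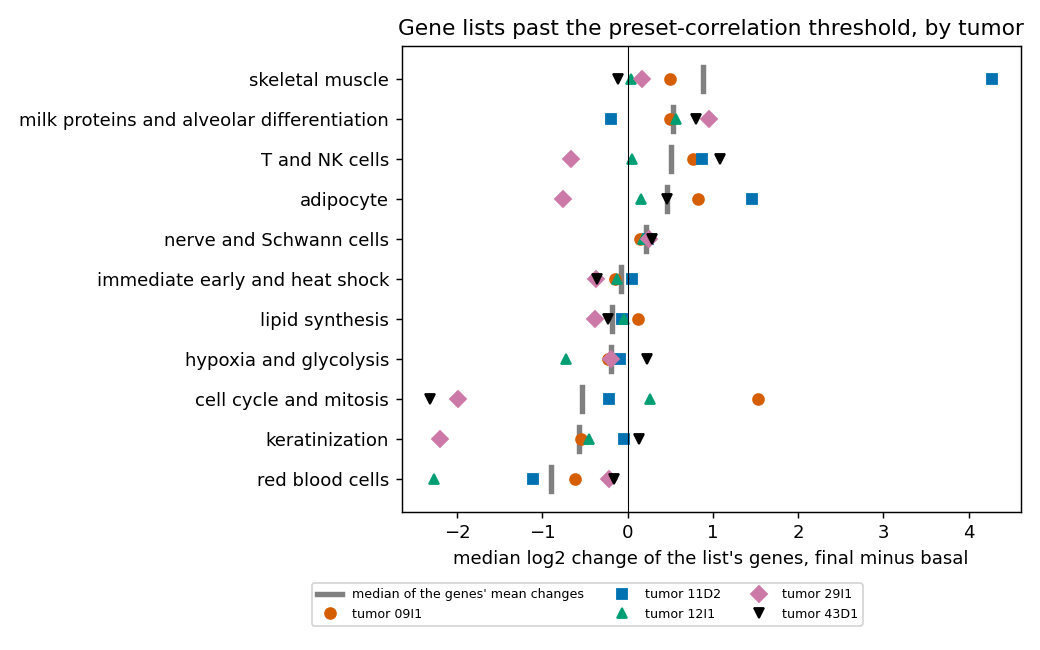
Median log2 change, final minus basal, of the genes of each list past camera's threshold at the preset correlation, with 1 point per tumor and a grey bar for the median of the genes' mean changes. Cell cycle medians run from -2.32 to 1.53, red blood cell medians are negative in all 5 tumors, and the skeletal muscle median is 4.28 in tumor 11D2.

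Keratinization genes, of the cornified epidermis, were lower, with a median of -0.56 over 14 members (camera adjusted p = 1.2e-05, and adjusted p = 0.591 with an estimated correlation). The list median was -2.20 in 29I1 and 0.14 in 43D1, and without 29I1 the median was -0.27 (adjusted p = 0.0017). Krtdap had a change of -2.42, Krt1 one of -1.73, Sprr1a one of -1.48 and Tgm1 one of -0.39. The final means of Krtdap (3.86) and Krt1 (3.57) lay below the lower quartile of every array, so the sizes of these 2 changes are uncertain. None of the keratinization list's members passed, over all probe sets or over the list alone. Hypoxia and glycolysis genes were lower with a median of -0.20 over 20 members (adjusted p = 2.3e-04, and 0.611 as the adjusted p with an estimated correlation). Vegfa, an angiogenic factor, had a change of -0.75 and was negative in 5 of 5 tumors, with Hk1 at -0.32, Eno1 at -0.23 and Ldha at -0.19. In 12I1 all 20 members were lower, and without 12I1 the list's median was -0.068 (adjusted p = 0.436). Lipid synthesis genes were lower with a median of -0.18 over 17 members (adjusted p = 7.8e-03, and adjusted p = 0.459 with an estimated correlation). Sqle, Elovl6 and Lss had changes of -0.44, -0.50 and -0.41, while Thrsp, a lipogenic regulator, had one of 2.15. Lss was at -1.19 in 09I1, and its change was -0.22 without that tumor. Without 29I1 the lipid synthesis list's median was -0.12 (adjusted p = 0.103), and without 43D1 the list's adjusted p was 0.064. Immediate early and heat shock genes were lower with a median of -0.075 over 23 members (adjusted p = 0.035, and adjusted p = 0.459 with an estimated correlation). Egr1, Egr2 and Ier3 had changes of -0.48, -0.38 and -0.65, each negative in 5 of 5 tumors, and Rgs1 one of 0.58. Its adjusted p was 0.055 without 12I1, 0.199 without 29I1 and 0.116 without 43D1, where its median was 0.042. That median was -0.011 without 29I1, -0.12 without 09I1 and -0.14 without 11D2. The immediate early list's adjusted p was 0.055 with cyclic loess and 0.173 with array weights, where that of lipid synthesis was 0.075. None of the members of these 3 lists passed, over all probe sets or over the list alone.

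T and NK cell genes were higher, with a median of 0.51 over 22 members (camera adjusted p = 1.2e-05, and adjusted p = 0.611 with an estimated correlation). The list median was 1.08 in 43D1 and -0.67 in 29I1, and without 43D1 the median was 0.27 (adjusted p = 0.032). In 43D1 macrophage genes had a list median of 0.89, with 21 of 21 higher, and 26 of 27 interferon response genes were higher. In 29I1 the macrophage list median was -1.27. Ccl5, a T cell chemokine, had a change of 0.81, with 2.34 in 43D1 and 0.12 to 1.14 in the other tumors. The granzymes Gzmk and Gzma had changes of 0.41 and 0.75, with Klrd1 at 0.53. Without 09I1 Gzma was at 0.38 and Klrd1 at 0.34. Adipocyte genes were higher with a median of 0.47 over 19 members (adjusted p = 2.0e-04, and adjusted p = 0.611 with an estimated correlation), with Pparg at 0.53, G0s2 at 0.77, Gpd1 at 0.41 and Aqp7 at 0.25. G0s2 was at 2.13 in 09I1, and its change was 0.43 without that tumor. The list median was 1.46 in 11D2 and -0.76 in 29I1, and the median was 0.16 without 11D2 (adjusted p = 0.10) and 0.78 without 29I1. In 11D2 fibroblast genes had a list median of 0.99, with 25 of 28 higher, the macrophage list median was 0.74, and 15 of 15 mast cell and eosinophil genes were higher. In 29I1 the list medians were -1.28 for fibroblast genes, with 27 of 28 lower, and -0.73 for endothelium. Skeletal muscle genes were higher with a median of 0.89 over 16 members (adjusted p = 1.2e-05, and adjusted p = 0.611 with an estimated correlation). The list median was 4.28 in 11D2 and between -0.11 and 0.49 in the other tumors, and the median was 0.16 without 11D2. With the lowest 50% of probe sets left out, the skeletal muscle list's adjusted p was 0.0503. In 11D2 the fast-muscle genes Myl11 and Actn3 had changes of 6.21 and 4.81, Pygm one of 3.28 and Atp2a1 one of 2.49. The basal mean of Myl11 (3.90) lay below the lower quartile of every array, so the size of its change is uncertain. Nerve and Schwann cell genes were higher with a median of 0.21 over 8 members (adjusted p = 0.039, and adjusted p = 0.459 with an estimated correlation), with Gfra3 at 0.39, Pmp22 at 0.22, S100b at 0.58 and Mbp at 0.34. Without 09I1, Gfra3 was at 0.32, Pmp22 at 0.22, S100b at 1.02 and Mbp at 0.68. The nerve list's adjusted p was 0.057 without a block and with a random block, and 0.11 without a filter. It was 0.093 with the mean of a gene's probe sets, 0.171 without 29I1 and 0.200 without 43D1. None of the members of these 4 lists passed, over all probe sets or over the list alone.

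The other 15 lists, DNA replication aside, did not pass the threshold with all 5 tumors weighted equally and the tumor as a fixed, not a random, block. Median changes were 0.027 for p53 target genes, -0.016 for luminal epithelium, -0.10 for myoepithelium and smooth muscle, -0.062 for fibroblast and extracellular matrix, 0.090 for endothelium and -0.083 for B cells. They were -0.10 for macrophages, 0.12 for mast cells and eosinophils, 0.045 for neutrophils, 0.033 for antigen presentation and 0.047 for interferon response. They were 0.040 for anthracycline target and metabolism genes, 0.039 for antioxidant defence, 0.029 for apoptosis regulators and 0.10 for oxidative phosphorylation. The median, mean and test differed in sign for 5 lists, namely endothelium, mast cells and eosinophils, neutrophils, antigen presentation and interferon response. With array weights, the median was 0.20 for antigen presentation (adjusted p = 0.026), 0.12 for interferon response (adjusted p = 0.026) and 0.24 for fibroblast genes (adjusted p = 0.011), with an adjusted p of 0.697 for each with an estimated correlation. Without a block, oxidative phosphorylation had an adjusted p of 0.046, and of 0.890 with an estimated correlation. With a random block its adjusted p was 0.047. Several of these lists passed with 1 tumor left out, at the preset correlation. Fibroblast genes had a median of -0.32 without 11D2 (adjusted p = 2.3e-05) and of 0.20 without 29I1 (adjusted p = 0.016), with adjusted p-values of 0.777 and 0.684 with an estimated correlation. Macrophage genes had one of -0.40 without 43D1 (adjusted p = 1.9e-05) and of -0.31 without 11D2 (adjusted p = 2.8e-04), with adjusted p-values of 0.745 and 0.777 with an estimated correlation. Without 29I1, the median was -0.34 for myoepithelium (adjusted p = 4.2e-05), 0.16 for endothelium (adjusted p = 0.033) and 0.14 for interferon response (adjusted p = 0.016). With an estimated correlation these adjusted p-values were 0.462, 0.462 and 0.642. Without 09I1 it was 0.12 for luminal epithelium (adjusted p = 0.013) and 0.091 for interferon response (adjusted p = 0.015), with adjusted p-values of 0.692 and 0.762 with an estimated correlation. Oxidative phosphorylation had a median of 0.16 without 43D1 (adjusted p = 0.0050, and adjusted p = 0.837 with an estimated correlation). Neutrophil genes, with a median of -0.32 without 09I1 (adjusted p = 0.090), did not pass with any tumor left out. Cdkn1a, the p53-induced cell cycle inhibitor, had a change of 0.62 and Mdm2, another p53 target, one of -0.18. By tumor, Cdkn1a ran from -0.54 in 12I1 to 1.66 in 43D1. Ccl11, an eosinophil chemokine, had a change of 3.21 and was positive in 4 of 5 tumors, with -0.46 in 29I1. S100a9 of neutrophils had a change of -1.37 and Rsad2, an interferon-induced gene, one of -1.32. Esr1, the oestrogen receptor, had a change of 0.077. Pgr, the progesterone receptor, had one of -0.25 with -3.52 in 09I1, and 0.56 without that tumor. Top2b had a change of -0.17, and 0.081 without 09I1.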

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

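Of the tests in this part, those on beta-actin, on the ends of the spike-ins, on the luminal list and on the red blood cell and platelet genes were chosen after the values had been seen. Among 130 sets of 5 values, 12 had a sample far from the other 4, where chance alone gives about 6.5.

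The final array of tumor 09I1 lay far from the other 4 final arrays in its 3' minus 5' difference for beta-actin (2.61) and GAPDH (0.93), in its poly-A controls (7.87) and in its bioB and bioC controls (9.33). These control values are part of the pattern, so they leave degraded or scarce RNA open without testing it. Incomplete labelling of all transcripts, spike-ins included, would raise the 3' minus 5' difference of the 4 poly-A spike-ins too. At 1.59, that difference lay within the 1.39 to 1.73 of the other 9 arrays, without an excess like that of beta-actin. It lay above their median and rests on 1 array, so incomplete labelling is not excluded. A change of the tumor's transcripts alone is argued against by probe sets of the same gene. Across 3672 genes, which are not independent replicates, the changes of 2 probe sets of a gene correlated at 0.44 in 09I1 and at 0.66 to 0.76 in the other 4 tumors. Real changes of the tumor beneath the loss of quality stay open.

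Cell cycle genes were higher in 09I1 and lower in 29I1 and 43D1. A shift of all genes of like signal alone is argued against. The list's median lay outside the middle 95% of 10000 signal-matched lists in 3 of these 3 tumors. The matched lists treat genes as independent, while this list's genes moved together (estimated correlation 0.84). The median lay outside in 11D2 and 12I1 too (percentiles 0.25 and 99.76), so this position does not set the 3 tumors apart. A lower share of luminal epithelial cells in the final samples of 29I1 and 43D1 is argued against too. The luminal list's median did not fall, at 0.20 in 29I1 and 0.18 in 43D1. It exceeded that of the cell cycle list by 2.19 and 2.50, more than the larger SD of the members (0.53 and 0.71). Most of that difference is the cell cycle fall that defined the pattern. The list of myoepithelium and smooth muscle had a median of 0.70 in 29I1 and -0.85 in 43D1, where 13 of 16 members were lower. A lower share of myoepithelial cells in 43D1 therefore stays open. Other shifts in cell mixture were not tested. The fibroblast list's median was -1.28 in 29I1, and the macrophage list's was 0.89 in 43D1. The cell cycle value in 09I1 rests on the array that stood apart. An effect of treatment was not tested, since no tumor was left untreated.

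The median of the red blood cell list was negative in all 5 tumors, at -0.22 in 29I1 and -0.15 in 43D1, each with 3 of 7 members positive. The quality of the 09I1 array is argued against as the source, as the median was -0.84 without that tumor, with a median below 0 in each of the other 4, while it was -0.47 without 12I1. Less blood in the final samples is a possible explanation. Of 11 tested platelet genes, 9 were lower, with a median of -0.43, but 5 of them had been looked at before. The other 6 had a median of -0.093, with 4 lower and a camera p of 0.263 at the preset correlation, so that less blood stays open. Treatment, age and a difference in the kind of sample stay open as untested.

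Single values far from the other 4 tumors were the skeletal muscle list in 11D2 (median 4.28), with Myl11 (6.21) and Actn3 (4.81) in it, and the endothelium list in 29I1 (median -0.73). Others were Thrsp in 12I1 (5.14), and Pgr (-3.52), Top2b (-1.19) and Cox5a (1.98) in 09I1.

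Chance was examined with 100 of the 126 ways to split the 10 arrays into groups of 5, the real one included. At the adjusted threshold the real count was 0 probe sets, which any split reaches, so that the 100 of 100 that did decide nothing. The highest other gave 3527. For the unadjusted count of 935, 45 gave as many, with a highest other of 7282, and for the 11 lists past the threshold 58 gave as many, with a highest other of 21. Chance is therefore not excluded for these last 2 counts. The splits with 3527 and 7282 parted only the pair of 09I1. With the tumor as a block they rest on that pair alone, give one and the same result, and restate that its final array stood apart. Only 16 splits part all 5 pairs as the real one does, too few for a share under 0.05. Among the 10 drawn, 4 gave at least 935 probe sets and 6 at least 11 lists, the real one included, with highest others of 1383 and 15. The other drawn splits parted 3 pairs (63 splits, at most 3270 probe sets and 21 lists) or 1 pair (27 splits, at most 7282 and 18).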

How the results depend on the processing

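The settings that combine a left-out tumor, array weights or no block with an estimated correlation, or leave out 09I1 and 11D2 together, were chosen after seeing the data. With limma, 0 probe sets passed in either direction under every alternative run, with and without a block, with each tumor left out, and with a fold threshold of 2 added. The unadjusted count was 935 with the block, 955 without a block and 957 with a random block, each of 23281 probe sets. It was 465 of the 15521 tested with the lowest 50% left out. It was 2440 with array weights (smallest adjusted p 0.0996), and 608 without 11D2 to 1868 without 09I1. The methods' paired t-test gave 525 higher and 556 lower at an unadjusted p under 0.05, where chance gives about 1164 in all. After adjustment it gave 0. Of lists, 5 were higher and 6 lower. With an estimated correlation, with fry, and with an estimated correlation without 09I1, 0 were higher and 0 lower. Among the 11 lists that passed at the preset correlation of 0.01, the estimated one ran from -0.11 (nerve) to 0.84 (cell cycle). It lay above the preset in all of these lists but the nerve list, so the preset took their genes as more independent than estimated. A higher correlation does not account for every lost call. The nerve list, below the preset, and the immediate early list, at 0.019, lost theirs too (adjusted p = 0.459 for each by camera with an estimated correlation). How far a higher correlation explains the other lost calls was not tested. With the lowest 50% left out, 4 were higher and 5 lower, as skeletal muscle no longer passed (adjusted p = 0.0503) and the red blood cell list, with that of B cells, had too few genes left to be tested. With array weights 8 were higher and 5 lower, and the cause was not tested. Without a block, 5 were higher and 6 lower and 10 of the 11 kept call and direction. The fixed block thus changed the call of the nerve list and, in the other direction, of oxidative phosphorylation (adjusted p = 0.046 without a block). A random block changed the same 2 calls, with an adjusted p of 0.057 for the nerve list and 0.047 for oxidative phosphorylation. Its estimated correlation within tumors was 0.0017, so this fit was nearly the one without a block. Its lists were tested with the form of camera that takes each gene's moderated statistic. With each tumor left out, 4 to 7 were higher and 4 to 8 lower, and 5 of the 11 lists kept call and direction in all 5 cases.

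Of 484 list values under alternatives, 359 kept direction and side of the threshold, 54 no longer passed, 17 newly passed and 54 had the opposite direction, 0 of these in a list that had passed. Of the 54, 49 passed in neither setting and 5 newly passed, namely fibroblast with array weights (adjusted p = 0.011) and without 29I1 (0.016), endothelium without 29I1 (0.033), and luminal epithelium without 09I1 (0.013) and without 09I1 and 11D2 (0.0065). With each tumor left out, with array weights and without a block, lists newly passed 16 times at the preset correlation, and 0 of these passed with an estimated correlation (adjusted p 0.462 to 0.890). Of 1437 values of named genes, 0 passed and 10 changed sign. The cause of the reversals was not tested, except that leaving tumors out removes their values. By camera direction, with medians given, anthracycline genes reversed without a block and with a random block (0.040). P53 targets (0.012) and antigen presentation (0.033) did without a filter, and endothelium with the lowest 50% left out (0.096). Antigen presentation did without a trend (0.033) and with the mean of probe sets (0.017). With fry, endothelium (0.090) and mast cells (0.12) did. With array weights, luminal epithelium (0.061), fibroblast (0.24), endothelium (0.095), macrophages (0.23), mast cells (0.13) and the gene Pgr (0.32) did. Without 09I1 and with an estimated correlation, luminal epithelium (0.12), myoepithelium (0.089), fibroblast (0.013), endothelium (0.013), mast cells (-0.021) and oxidative phosphorylation (-0.012) did. Without 09I1 and 11D2, luminal epithelium (0.15), myoepithelium (0.14), anthracycline genes (-0.070), antioxidant defence (-0.096), oxidative phosphorylation (-0.058) and the genes Spdef (-6.0e-04), Cox5b (-0.058), Top2b (0.14) and Pgr (0.67) did.

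With 1 tumor left out, medians ran from -0.025 to 0.063 for p53 targets, -0.47 to 0.15 for DNA replication, -0.083 to 0.12 for luminal epithelium, -0.34 to 0.089 for myoepithelium and -0.32 to 0.20 for fibroblast. They ran from -0.026 to 0.16 for endothelium, -0.20 to 0.062 for B cells, -0.40 to 0.21 for macrophages, -0.28 to 0.28 for mast cells and -0.32 to 0.19 for neutrophils. They ran from -0.082 to 0.11 for antigen presentation, -0.033 to 0.14 for interferon response, 0.0017 to 0.080 for anthracycline genes, 0.0021 to 0.11 for antioxidant defence and -0.012 to 0.16 for oxidative phosphorylation. Changes ran from -0.41 to 0.0095 for Jchain, -0.28 to 0.081 for Top2b, -0.083 to 0.31 for Esr1 and -0.59 to 0.56 for Pgr. No detection calls were used, so how far signal over background limits dim genes is open.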

Other observations

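Genes of the circadian clock, a group in none of the lists above, were examined after Npas2 and Tef had been seen among genes of the same sign in all 5 tumors, and the test here was chosen after that. Npas2, a partner of Bmal1 in the clock's activating complex, had a change of 1.20 and was positive in 5 of 5 tumors. Bmal1 had a change of 0.85, positive in 4 of 5, and Nfil3 one of 0.66. Genes that peak in the opposite phase were lower, with Per3 at -1.52, Dbp at -1.15, Per2 at -1.09 and Tef at -0.74, each negative in 5 of 5 tumors. Not all members moved this way. Clock had a change of -0.33, Cry1 one of -0.20, Per1 one of 0.27 and Bhlhe41 one of 0.44, and none of these genes passed the threshold in limma.

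A hypothesis is that the final samples were taken at another time of day than the biopsies. Without Npas2 and Tef, the 4 tested genes that peak with Bmal1 had a median change 0.65 above that of the 8 that peak with Dbp. This lay at percentile 99.97 of 10000 random sets of like signal, a description that treats genes as independent. The difference was positive in 5 of 5 tumors, from 0.15 to 1.72, and was 0.76 without 09I1. Much of it rests on Per3, Dbp and Per2, as without these 3 genes, left out because of their values, it was 0.40 (percentile 98.99). The result is consistent with the hypothesis, but the time of sampling is not given in the sources used here. Treatment and age differ between the groups in the same way, the kind of sample may too, and all stay open.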
